A study of Mus musculus with 98 samples.

How the data were processed

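The study measured DNA methylation by reduced representation bisulfite sequencing of mouse embryos, 1 library per sample, in 98 libraries that the labels place in 25 groups by embryo type, added factor and stage. Reads were aligned with BSMAP 2.89 to the mouse build mm9, per the submitters' processing notes. Each deposited file lists CpG positions with a raw count of the reads calling the site, per the file headers, with no normalization found in the values. The same deposited files give, per the file headers, the fraction of those reads that call C (methylated) and T (unmethylated), written to 3 decimals. Multiplying the count by the fraction gave whole numbers of methylated calls within that rounding at 100% of the checked sites of every library. Read trimming, duplicate handling and any filter before these steps are stated neither in the headers nor in the labels.

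Positions were kept as the files give them, on mm9. The only gene table at hand is for another mouse build, so no gene was named from a coordinate. Mean CpG methylation of a library was the unweighted mean of the methylated percentage over CpG positions with at least 5 calls on chromosomes 1 to 19 and X. Calls on chromosome Y and on the mitochondrial genome were left out of the main measurements. The same mean was taken for the X chromosome alone. CpG positions were also placed into fixed tiles of 300 bp, and a tile counted in a library when it held at least 2 positions of at least 5 calls and 10 calls in all. Tiles were classed by their number of distinct CpG positions seen in any library, at any coverage. The classes were low (2 to 5), intermediate (6 to 14) and high density (15 or more). They count observed positions and need not follow the CpG density of the genome.

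Libraries held 2359993 to 104255493 calls, 96414 to 1022786 positions with at least 5 calls (median 481709), and a median coverage of 10 to 67 calls at those positions. Over all libraries 3121281 distinct CpG positions were seen, and 206456 tiles were covered in 4 or more libraries. The named tiles had 10 to 10867 calls per library, and percentages at the lower end of that range are coarse. Reads carry no molecular identifiers, so call numbers overstate independent molecules and counting error is a lower limit on the error. No 2 replicates of a group looked like copies of 1 library: over 183 pairs the correlation of tile values was 0.492 to 0.854.

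Group means were compared with exact two-sided permutation tests over all splits of the libraries, with Benjamini-Hochberg adjustment over 34 comparisons for each measure. Differences between trophectoderm and inner cell mass in the effect of embryo type were tested by exact permutation of the lineage labels within each embryo type. They were adjusted over 7 tests for each measure. Tiles were tested with the quasi-likelihood test of edgeR 4.0.16 on methylated and unmethylated counts, with 1 effect per library and a coefficient for the methylated share by group, on tiles covered in at least 3 libraries of each group (both libraries of a group of 2). The common dispersion came from up to 4000 randomly chosen tiles. Tiles wholly methylated or wholly unmethylated in every library were not tested. A tile was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of group means of at least 20 percentage points. Named regions are, for each comparison and direction, the 3 called tiles with the largest difference among those whose libraries do not overlap between the groups, with ties broken by smaller p and then by position.

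The tile test was tested on simulated data, drawn with the real coverage and 1 average spread between libraries for all tiles of a comparison. In each, 200 of 8000 tiles were changed, or 200 of 4075 for Kdm5b from 2-cell to 4-cell. That spread was estimated from observed percentages, which already hold counting error. A shift of 80 points was recovered in 82.5% of changed tiles for clones against fertilised embryos at the 1-cell stage, 85% for the same contrast in the trophectoderm, 99.5% for Kdm4b against unmodified clones in the trophectoderm, 96.5% for Kdm5b from 2-cell to 4-cell, and 57% for siDnmt3a. For a shift of 40 points the shares were 0%, 1%, 12.5%, 1.5% and 0% in the same order, so a low number of calls does not mean few changes. The share recovered also depends on how many tiles change. In the real data edgeR called 16.9% of tested tiles for clones at the 1-cell stage, so these shares need not hold there. Among unchanged tiles 3.18% to 4.00% had an unadjusted p under 0.05.

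Groups, tests, the rule for named regions and most alternatives were chosen before the data were examined. These alternatives were a CpG coverage minimum of 10 or 1 calls, tiles of 1000 bp, a tile minimum of 30 calls, limma 3.58.1 on log2 ratios with 1 added to each count, pooled calls in place of the mean over positions, tiles covered in every library, the replicate number as a block, and leaving out each library of a group of 2 to 5. Means over tiles shared by each pair of libraries, and the tests between the lineages with their alternatives, were added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.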

Results

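DNA methylation was measured by reduced representation bisulfite sequencing in 98 libraries of mouse preimplantation embryos of the strain B6D2F1. Of these, 9 came from fertilised embryos and 89 from embryos made by nuclear transfer, called clones here. Fertilised embryos and unmodified clones had 3 libraries each at the 1-cell stage, in the inner cell mass and in the trophectoderm. Another 6 libraries came from clones of 4-cell stage that had arrested as 2-cell embryos. The remaining clones carried Kdm4b, Kdm5b or Kdm4b+Kdm5b in their labels and were sampled at the 1-cell, 2-cell and 4-cell stages and in both blastocyst lineages, with 2 to 10 libraries per group. Kdm4b encodes a demethylase of histone H3 lysine 9 and Kdm5b a demethylase of histone H3 lysine 4, and the labels give neither how they were supplied nor the dose. A last set of 4-cell clones was labelled Low Kdm4b+Kdm5b, alone (3 libraries), with siDnmt3a (2 libraries) or with siDnmt3b (2 libraries). Dnmt3a and Dnmt3b encode the de novo DNA methyltransferases, and the labels do not say what Low refers to. Total CpG calls per library ran from 2359993 to 104255493, and 96414 to 1022786 CpG positions per library had at least 5 calls. Nothing in the labels says that replicates came from separate cultures or embryo pools, so the p-values measure only the spread between these samples.

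The comparison of clones with fertilised embryos at the 1-cell stage shows what methylation a clone starts from. Mean CpG methylation was 42.6% ± 3.62 (SD, n = 3) in clones and 30.2% ± 1.88 (SD, n = 3) in fertilised embryos, a difference of 12.3 percentage points. On the X chromosome the gap was larger, with 73.6% ± 1.52 against 46.9% ± 2.55, and the difference came to 26.6 points. The excess was present in every density class: tiles of low density stood at 58.4% against 41.5%, and tiles of high density at 27.0% against 18.2%. All 3 cloned libraries lay above all 3 fertilised ones in each of these measures. The exact two-sided permutation test gave p = 0.1 for mean methylation, the smallest value that 3 libraries against 3 allow, and 0.262 after adjustment over the 34 comparisons of means.

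At the level of 300-bp tiles, 2504 of 15200 tested tiles were more methylated in 1-cell clones than in fertilised 1-cell embryos and 62 were less methylated, at an adjusted p under 0.05 by edgeR and a difference of at least 20 points. Tiles whose libraries did not overlap made up 50.4% of the 15516 covered tiles, against the 10% that chance gives for 3 against 3. The number of called tiles was 1182 without cloned replicate 1, 1194 without cloned replicate 2, and 1164, 1251 and 1236 without fertilised replicates 1, 2 and 3. Most of the calls were upward in each of these fits. Limma called 3621 tiles.

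The most positive called tile at the 1-cell stage, chromosome 13 from 81955801 to 81956100 (mm9), was at 99.96% ± 0.079 (SD, n = 3) in clones and 0% in all 3 fertilised libraries, with an edgeR adjusted p of 0.00407. Tiles at chromosome 3, 20815801 to 20816100, and chromosome 17, 40252201 to 40252500, had differences of 99.7 and 99.6 points, with edgeR adjusted p-values of 0.00898 and 0.0117. In the other direction, the tile at chromosome 2, 122175001 to 122175300, was at 0.0395% in clones and 99.1% in fertilised embryos, with an edgeR adjusted p of 0.0052. Differences of -98.6 and -97.0 points were found at chromosome 6, 54223501 to 54223800, and chromosome 7, 25991101 to 25991400, with edgeR adjusted p-values of 0.0246 and 0.0309. The first tile was no longer called without cloned replicate 2 (difference 100 points), nor the chromosome 2 tile without cloned replicate 1 (-99.1 points). Chromosome 3 lost its call without any 1 of the fertilised replicates (99.5 to 100 points) and chromosome 17 without any 1 of the cloned replicates (99.4 to 100 points). Chromosome 6 was called only without cloned replicate 3 (-100 to -97.8 points over the 6 fits), and chromosome 7 in 0 of the 6 fits (-99.5 to -95.5 points).

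In the blastocyst, clones exceeded fertilised embryos in the trophectoderm, the lineage that forms the placenta. Cloned trophectoderm had a mean CpG methylation of 22.7% ± 1.80 (SD, n = 3) and fertilised trophectoderm 11.6% ± 1.92 (SD, n = 3), so clones were 11.1 points higher, with no overlap between the libraries. In the inner cell mass the corresponding levels were 15.1% ± 2.17 and 16.9% ± 1.49, a difference of -1.80 points that lay within the spread between replicates. It changed sign over tiles covered in every library (0.458 points) and over tiles shared by each pair of libraries (0.667 points). On the X and at low density of the tiles covered in every library, clones lay above fertilised embryos without overlap in the inner cell mass too, by 4.69 and 2.44 points (exact permutation p = 0.1 each, adjusted 0.136 and 0.155). Fertilised embryos were 5.31 points higher in the inner cell mass than in the trophectoderm, whereas in clones the inner cell mass was lower by 7.62 points. Exact permutation tests gave p = 0.1 (adjusted 0.262) for the trophectoderm and p = 0.4 (adjusted 0.544) for the inner cell mass, where 0.1 is again the smallest value possible.

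The clone effect differed between the lineages. Clones exceeded fertilised embryos by 12.9 points more in the trophectoderm than in the inner cell mass. Exact permutation of the lineage labels within each embryo type gave p = 0.005 for this (adjusted 0.0222 over 7 such tests). On the X chromosome this difference between the lineages was 23.7 points (exact permutation p = 0.005, adjusted 0.0172). The labels do not say whether inner cell mass and trophectoderm libraries came from the same embryos, and the permutations treat them as independent. Their null is that neither embryo type differs between the lineages. If the lineages shared embryos, these p-values would not hold. A joint permutation of the embryo types, 3 against 3, would then have only 20 splits, and its p could not be under 0.1. Cloned and fertilised X chromosomes were at 47.9% ± 3.59 and 22.1% ± 4.12 (SD, n = 3 each) in the trophectoderm, and at 32.3% ± 3.75 and 30.2% ± 2.57 in the inner cell mass. Sex is not given in the labels. Calls on the Y, in ppm of the calls on autosomes and X, were 56.4 to 71.3 in cloned and 78.0 to 219 in fertilised trophectoderm, and 70.5 to 77.5 against 116 to 211 in the inner cell mass.

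**Figure D1:**
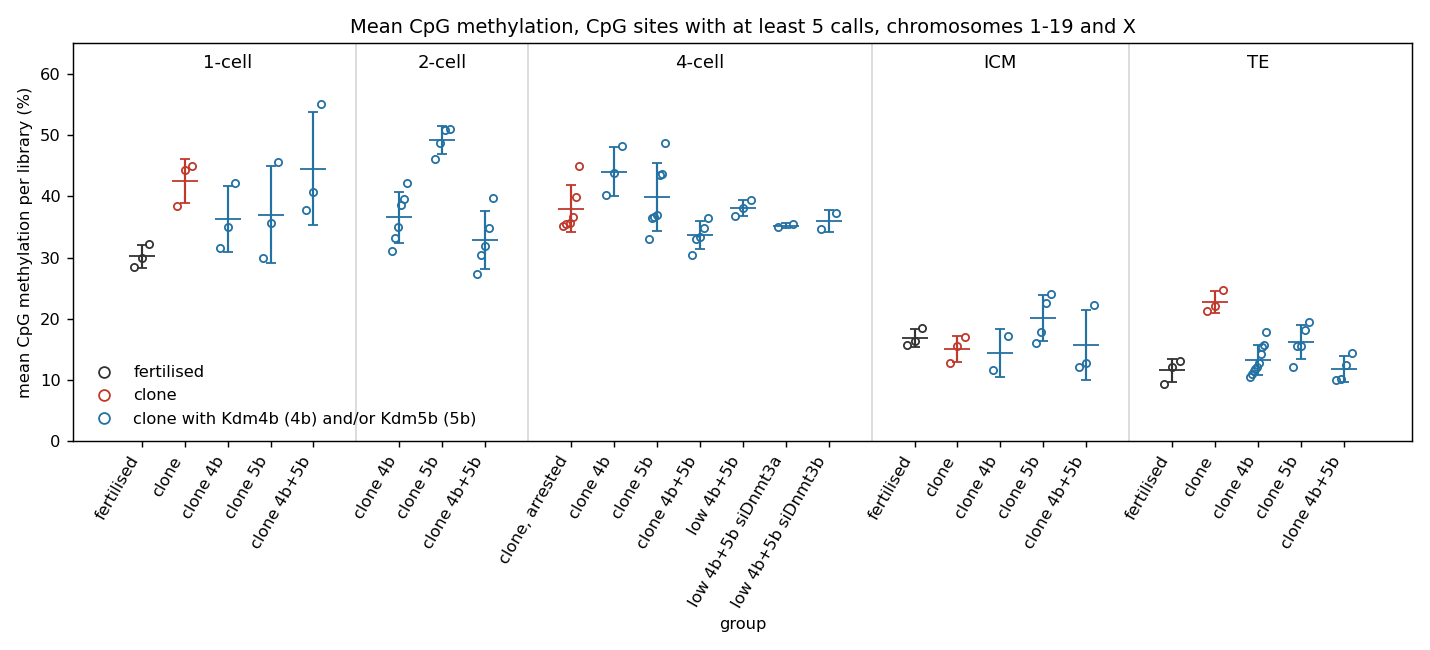
Mean CpG methylation in percent (vertical axis) for each group (horizontal axis), with 1 point per library and the group mean and SD. The 3 cloned trophectoderm libraries lie between 21.3% and 24.8%, above the fertilised trophectoderm libraries at 9.43% to 13.1%.

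The trophectoderm excess was larger in tiles with few observed CpG positions. Tiles of low CpG density (2 to 5 positions) were at 44.4% ± 5.61 in cloned and 18.3% ± 1.70 in fertilised trophectoderm (SD, n = 3 each), a gap of 26.1 points. Tiles of high density (15 positions or more) were at 10.2% ± 0.884 against 6.34% ± 1.18, a gap of 3.87 points. By edgeR, 3140 of 47707 tested tiles were higher in cloned trophectoderm and 23 lower, and limma called 6221. The called tiles included 994 higher and 3 lower of 9562 at low density and 652 higher and 9 lower of 21201 at high density. Tiles with no overlap between the libraries made up 37.0% of the 48278 covered tiles, where chance gives 10% for 3 against 3. Calls were 599, 226 and 1335 without cloned replicates 1, 2 and 3, none of them lower in clones in the first 2 cases and 3 lower in the last.

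In the inner cell mass edgeR called 0 of 56616 tiles, and limma also called 0. At an unadjusted p under 0.05 there were 8442 tiles, 4298 higher and 4144 lower in clones. They were 14.9% of those tested, against 3.18% to 4.00% of unchanged tiles in simulated data of other comparisons. Tiles with no overlap made up 24.8% of the 57106 covered tiles, where chance gives 10% for 3 against 3, so differences in both directions are not excluded in this lineage. The tiles called higher in cloned trophectoderm nevertheless differed in the inner cell mass as well: over those of the 3140 tiles that each library covered, they averaged 32.2% in cloned and 12.7% in fertilised inner cell mass. They averaged 58.6% in cloned and 5.16% in fertilised trophectoderm, the libraries in which they were selected.

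Chromosome 12 held the most positive trophectoderm tiles, at 108789001 to 108789300 with 97.4% ± 4.44 in clones against 0.292% ± 0.506 in fertilised embryos (SD, n = 3 each; edgeR adjusted p 0.0086), and the adjoining 108789301 to 108789600 with a difference of 97.1 points (edgeR adjusted p 0.0112). The third, at chromosome 7, 4983601 to 4983900, differed by 96.1 points (edgeR adjusted p 0.00853). These 3 tiles lost their call only without cloned replicate 2, with differences of 95.9, 95.7 and 96.2 points. The most negative tiles lay at chromosome 1, 38341501 to 38341800, chromosome 8, 72345901 to 72346200, and chromosome 3, 123023401 to 123023700, with differences of -59.5, -56.2 and -52.8 points and edgeR adjusted p-values of 0.0381, 0.0342 and 0.0397. Each of these last tiles lost its call without any 1 of the 3 cloned replicates, where their differences lay between -59.5 and -52.1 points. Chromosome 1 also lost it without fertilised replicate 1 or 3 (-60.1 and -57.7 points), and chromosome 3 without fertilised replicate 1 (-36.3 points).

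Clones with Kdm4b, Kdm5b or both were compared with unmodified clones in the trophectoderm to learn whether the excess was smaller with the demethylases. Mean CpG methylation was 13.3% ± 2.39 (SD, n = 10) with Kdm4b, 16.2% ± 2.79 (SD, n = 5) with Kdm5b and 11.8% ± 2.13 (SD, n = 4) with Kdm4b+Kdm5b, against 22.7% in unmodified clones. The differences were -9.44, -6.55 and -10.9 points, and every library with a demethylase lay below every unmodified one. Exact permutation p-values were 0.0035, 0.0357 and 0.0286, the last being the smallest that 4 against 3 allow, and 0.119, 0.233 and 0.233 after adjustment over the 34 comparisons. Over tiles covered in every library of a comparison the differences were -17.2, -13.5 and -19.1 points.

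The demethylase groups were also compared with fertilised trophectoderm. They differed from its 11.6% by 1.69, 4.58 and 0.193 points with Kdm4b, Kdm5b and Kdm4b+Kdm5b (exact permutation p = 0.304, 0.0893 and 0.914). Over tiles covered in every library the first and last changed sign, to -1.32 and -3.10 points, and the Kdm5b difference was 1.71 points (exact permutation p = 0.214). Every Kdm4b+Kdm5b library then lay below every fertilised one, by -7.68 points on the X (exact permutation p = 0.0286 for both). With pooled calls mean methylation was 17.2%, 22.6% and 16.1% with Kdm4b, Kdm5b and Kdm4b+Kdm5b, against 14.96% in fertilised trophectoderm. X methylation was 26.6% ± 4.80 (SD, n = 10), 31.1% ± 4.22 (SD, n = 5) and 19.9% ± 2.75 (SD, n = 4), against 47.9% in unmodified clones and 22.1% in fertilised embryos. Differences on the X from unmodified clones were -21.3, -16.8 and -28.0 points (exact permutation p = 0.0035, 0.0179 and 0.0286, adjusted 0.0594, 0.152 and 0.194). At low CpG density the groups stood at 20.02%, 24.3% and 16.7%, against 44.4% in unmodified and 18.3% in fertilised trophectoderm.

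**Figure D2:**
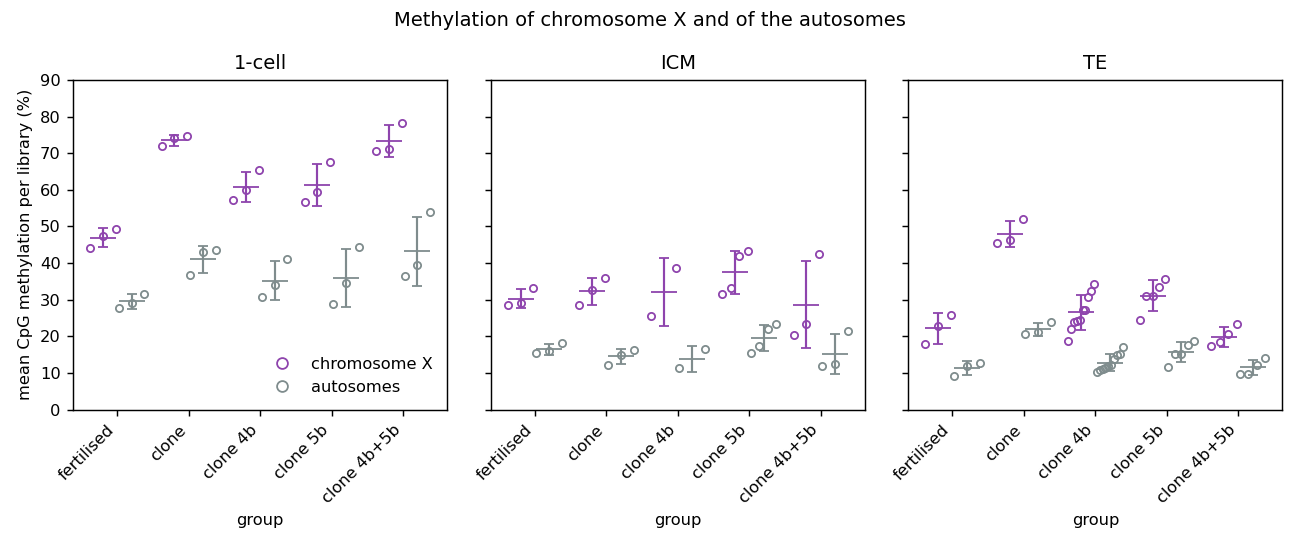
Methylation of the X chromosome and of the autosomes in percent (vertical axis) by group (horizontal axis), with panels for the 1-cell stage, inner cell mass and trophectoderm. Each library has 1 point for the X and 1 for the autosomes, with the group mean and SD. On the X, unmodified clones have a mean of 47.9% in the trophectoderm, against 22.1% in fertilised embryos and 19.9% in clones with Kdm4b+Kdm5b.

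Every trophectoderm tile called by edgeR between demethylase clones and unmodified clones was lower with the demethylase. There were 7038 of 68251 tested tiles with Kdm4b, 212 of 66147 with Kdm5b and 2472 of 58160 with Kdm4b+Kdm5b. At an unadjusted p under 0.05 the tiles lower and higher numbered 24101 and 197, 13486 and 505, and 19186 and 393. The limma counts were 17769, 0 and 14104. The counts by edgeR changed with single libraries. Without unmodified replicates 1, 2 and 3 the Kdm4b count was 1374, 225 and 500, and the 10 Kdm4b libraries were not left out in turn. The Kdm5b count was 246, 0 and 0 without unmodified replicates 1, 2 and 3, and 1, 1, 0, 75 and 130 without Kdm5b replicates 1 to 5. With Kdm4b+Kdm5b it was 755, 583 and 334 without unmodified replicates 1, 2 and 3, and 812, 1325, 548 and 1700 without Kdm4b+Kdm5b replicates 1 to 4.

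The tiles called higher in cloned than in fertilised trophectoderm had lower levels in all 3 demethylase groups. Their mean was 21.6% with Kdm4b, 27.8% with Kdm5b and 18.2% with Kdm4b+Kdm5b, between the 5.16% of fertilised and the 58.6% of unmodified cloned trophectoderm. Selection on high values in the unmodified clones and low values in fertilised embryos can by itself place other groups between them. Tiles are also not independent replicates. At the tested tiles not called higher, the levels were 13.3%, 16.1% and 11.4% with Kdm4b, Kdm5b and Kdm4b+Kdm5b. There, fertilised trophectoderm was at 15.5% and unmodified cloned trophectoderm at 27.5%. The values at the called tiles therefore do not show whether the demethylase groups stayed above the fertilised level.

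**Figure D3:**
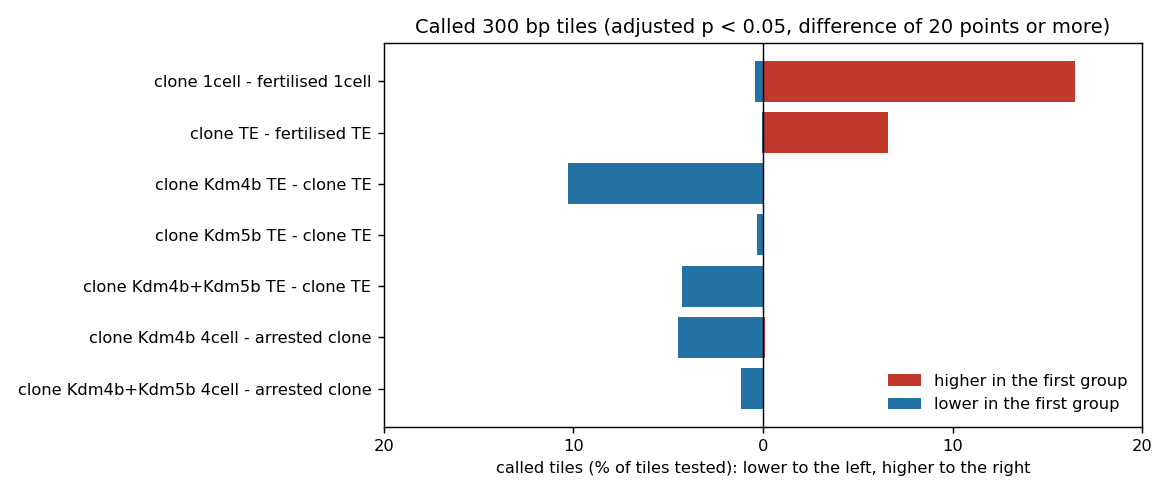
Tiles of 300 bp called higher or lower by edgeR, in percent of the tiles tested (horizontal axis), by comparison (vertical axis). Only comparisons with multiple called tiles are drawn. Cloned trophectoderm has 3140 of 47707 tested tiles higher than fertilised trophectoderm. Kdm4b clones have 7038 of 68251 tested tiles lower than unmodified clones in that lineage.

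Among the named trophectoderm tiles, chromosome 2, 30945901 to 30946200, was selected in both single-demethylase comparisons. It was at 12.0% ± 9.09 (SD, n = 10) with Kdm4b, 19.4% ± 7.33 (SD, n = 5) with Kdm5b and 96.1% ± 3.36 (SD, n = 3) in unmodified clones (edgeR adjusted p 0.00531 and 0.0267). The Kdm4b call there ended without unmodified replicate 2 or 3 (-85.0 and -82.2 points), and the Kdm5b call ended without any 1 of the unmodified replicates or Kdm5b replicate 1, 2 or 3 (-77.8 to -74.8 points). With Kdm4b the most negative tile, chromosome 2, 75855901 to 75856200, was at 3.47% ± 5.29 (SD, n = 9) against 94.6% ± 5.05 (SD, n = 3) and stayed called in all 3 such fits (edgeR adjusted p 0.00289). Next came chromosome 2, 53641501 to 53641800, with -85.6 points (edgeR adjusted p 0.0306), covered in 3 of the 10 Kdm4b libraries and called in 0 of 3 such fits (-87.9 to -83.3 points). With Kdm5b the others were chromosome 5, 111612301 to 111612600 (-78.4 points), and chromosome 19, 16158601 to 16158900 (-76.9 points), with edgeR adjusted p-values of 0.0303 and 0.0302. Kdm5b replicate 4 did not cover either tile. Both lost their call without any 1 of the libraries that covered them (-83.4 to -74.7 and -81.9 to -72.4 points). With Kdm4b+Kdm5b they were chromosome 14, 78180901 to 78181200 (-93.0 points, edgeR adjusted p 0.00804), chromosome 2, 171563101 to 171563400 (-91.4 points, 0.0117), and chromosome 3, 54436501 to 54436800 (-89.5 points, 0.00754). Of these, the first 2 lost their call without unmodified replicate 2 or 3 (-93.2 and -92.8 points on chromosome 14, -89.1 and -89.9 on chromosome 2) and the third was called in all 7 fits.

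In the inner cell mass the demethylase groups overlapped with unmodified clones in mean methylation. Mean CpG methylation was 14.4% ± 3.86 (SD, n = 2) with Kdm4b, 20.1% ± 3.78 (SD, n = 4) with Kdm5b and 15.7% ± 5.71 (SD, n = 3) with Kdm4b+Kdm5b, against 15.1% ± 2.17 (SD, n = 3). Differences were -0.684, 5.05 and 0.577 points (exact permutation p = 0.8, 0.143 and 1). Over tiles covered in every library the Kdm5b difference was 1.76 points (exact permutation p = 0.371) and the Kdm4b+Kdm5b one changed sign, to -1.58 points, and Kdm4b lay below unmodified clones without overlap on the autosomes (-1.22 points) and at low density (-1.79 points; exact permutation p = 0.2 each). By edgeR and by limma 0 tiles were called in each of the 3 comparisons, with 3089, 2589 and 1990 tiles at an unadjusted p under 0.05. The demethylase effect on mean methylation was more negative in the trophectoderm than in the inner cell mass by -8.76 points with Kdm4b, -11.6 with Kdm5b and -11.5 with Kdm4b+Kdm5b (exact permutation p = 0.0326, 0.00635 and 0.0114, adjusted 0.057, 0.0222 and 0.0267). On the X chromosome the same differences were -21.2, -22.0 and -24.4 points, each with an exact permutation p adjusted to 0.0172. Without Kdm4b replicate 1 of the inner cell mass the Kdm4b value passed (-11.5 points). The Kdm4b+Kdm5b value no longer passed without trophectoderm replicate 1 or 3 (-11.0 and -10.9 points) or inner cell mass replicate 3 (-8.22 points), and on the X the Kdm4b value no longer passed without inner cell mass replicate 2 (-14.6 points).

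At the 1-cell stage, clones with a single demethylase had lower means than unmodified clones. Mean CpG methylation was 36.3% ± 5.36 with Kdm4b, 37.0% ± 7.93 with Kdm5b and 44.5% ± 9.26 with Kdm4b+Kdm5b, against 42.6% ± 3.62 (SD, n = 3 each). The differences of -6.29, -5.53 and 1.96 points were not larger than the spread between replicates could give (exact permutation p = 0.2, 0.4 and 0.9), and over pooled calls the last was -6.60 points. Leaving out 1 library at a time, the Kdm4b difference ran from -9.23 (without Kdm4b replicate 1) to -3.98 (without Kdm4b replicate 2). For Kdm5b it ran from -9.81 (without Kdm5b replicate 2) to -1.97 (without Kdm5b replicate 3). X methylation was 60.8% ± 4.16, 61.2% ± 5.71 and 73.3% ± 4.29, against 73.6% ± 1.52 (SD, n = 3 each). The single demethylases had no overlap with unmodified clones on the X, by -12.8 and -12.3 points (exact permutation p = 0.1 each, the smallest possible). The single demethylases were also below unmodified clones without overlap over tiles covered in every library of a comparison, by -5.21 and -4.07 points over all tiles, -6.78 and -5.79 on the X and -8.74 and -6.98 at low density (exact permutation p = 0.1 each). EdgeR and limma called 0 tiles in all 3 comparisons. At an unadjusted p under 0.05, 1649 tiles were lower and 138 higher with Kdm4b, and 1129 lower and 122 higher with Kdm5b, while Kdm4b+Kdm5b had 94 lower and 170 higher.

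Clones with demethylases that reached the 4-cell stage were compared with clones that had arrested as 2-cell embryos. The arrested clones carried no demethylase by their labels and every 4-cell group compared with them did, so development and demethylase are fully confounded here. Arrested clones had a mean CpG methylation of 38.0% ± 3.83 (SD, n = 6) and an X methylation of 67.5% ± 3.42. With Kdm4b+Kdm5b the 4-cell clones had 33.7% ± 2.24 (SD, n = 5) overall and 54.3% ± 3.88 on the X. These differences were -4.29 points (exact permutation p = 0.0411, adjusted 0.233) and -13.1 points (exact permutation p = 0.00216, adjusted 0.0594), the latter with every 4-cell library below every arrested one. They were -8.98 points over tiles covered in every library, with no overlap, and -11.0 points on the X portion of these, with overlap. With Kdm4b the 4-cell level was 44.1% ± 3.96 (SD, n = 3), 6.08 points above arrested clones (exact permutation p = 0.0833), and with Kdm5b 39.9% ± 5.53 (SD, n = 7), 1.91 points above (exact permutation p = 0.496). On the X these groups were not above arrested clones, at 64.7% and 65.8% (-2.82 and -1.65 points, exact permutation p = 0.345 and 0.517). At intermediate density they were at 50.3% and 51.4%, against 51.9%. They were above arrested clones at low density (52.96% and 54.99%, against 52.45%) and at high density (30.9% and 26.0%, against 23.0%). In mean methylation over tiles covered in every library both of these groups changed sign, to -11.2 and -3.17 points, so their direction on each library's own sites was not that on common sites.

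By edgeR, Kdm4b 4-cell clones had 269 tiles lower and 5 higher than arrested clones among 6023 tested, and Kdm4b+Kdm5b clones had 77 lower and 3 higher among 6546 (limma 291 and 140 tiles). Kdm5b clones had 0 of 10690 by edgeR and 0 by limma, with 552 at an unadjusted p under 0.05. The Kdm4b count was 94, 171 and 74 without Kdm4b replicates 1, 2 and 3, and 0 with the replicate number as a block. The Kdm4b+Kdm5b count was 129 without its replicate 3.

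The most negative of these tiles, chromosome 8, 125957701 to 125958000, was at 7.40% ± 7.79 with Kdm4b+Kdm5b and 96.6% ± 3.82 in arrested clones (SD, n = 5 each; edgeR adjusted p 0.00736) and was called in all 5 fits without 1 library. The other two lay on the X at 27027601 to 27027900 (-74.7 points, edgeR adjusted p 0.012) and 28035601 to 28035900 (-62.7 points, edgeR adjusted p 0.00556), each covered in 3 of 5 Kdm4b+Kdm5b libraries. Higher with Kdm4b+Kdm5b were chromosome 8, 107219101 to 107219400 (77.8 points), and chromosome 5, 38706601 to 38706900 (65.7 points) and 113555401 to 113555700 (24.2 points), with edgeR adjusted p-values of 0.015, 0.0198 and 0.0329. Each of these was covered in only 3 of 5 Kdm4b+Kdm5b and 3 of 6 arrested libraries. With Kdm4b the tiles higher than in arrested clones lay on chromosome 13 at 66969001 to 66969300, 65991901 to 65992200 and 65991601 to 65991900, with differences of 83.2, 80.9 and 65.6 points (edgeR adjusted p 0.0419, 0.0273 and 0.00904). The lower ones were chromosome 1, 168531301 to 168531600 (-68.3 points), and chromosome 10, 33587101 to 33587400 (-60.7 points) and 129030601 to 129030900 (-58.6 points), with edgeR adjusted p-values of 0.0337, 0.0356 and 0.00875. Each Kdm4b tile lost its call without Kdm4b replicate 2 (64.8 to 82.0 points for the first 3 and -77.3 to -54.2 for the last 3). Without replicate 1 all but 65991601 to 65991900 lost it (80.9 to 84.9 and -60.8 to -51.3 points), and without replicate 3 all but 129030601 to 129030900 (64.6 to 82.8 and -73.8 to -61.4 points).

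Between the 2-cell and the 4-cell stage the direction of the differences depended on which sites were compared. Kdm4b clones were at 36.6% ± 4.18 (SD, n = 6) and 44.1% ± 3.96 (SD, n = 3), Kdm5b clones at 49.2% ± 2.31 (SD, n = 4) and 39.9% ± 5.53 (SD, n = 7), and Kdm4b+Kdm5b clones at 32.8% ± 4.73 and 33.7% ± 2.24 (SD, n = 5 each). The differences were 7.46, -9.29 and 0.837 points (exact permutation p = 0.0357, 0.00909 and 0.77, adjusted 0.233, 0.155 and 0.877). Over tiles covered in every library they became -5.79, -0.307 and -3.75 points, and over tiles shared by each pair of libraries, an alternative chosen after seeing the data, the Kdm5b difference was 0.366 points. Without Kdm4b+Kdm5b 2-cell replicate 4 the last was -0.532 points. EdgeR called 1 tile with Kdm4b, chromosome 12, 69508501 to 69508800, at 70.6% ± 2.74 (SD, n = 3) in 4-cell and 91.4% ± 2.07 (SD, n = 6) in 2-cell clones (edgeR adjusted p 0.0338), and 0 without any 1 of the 3 Kdm4b 4-cell replicates (-22.4 to -19.9 points). It called 0 tiles with Kdm5b and Kdm4b+Kdm5b, limma called 0 in all 3 comparisons, and 770, 239 and 416 tiles had an unadjusted p under 0.05.

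The last comparison asks whether Low Kdm4b+Kdm5b 4-cell clones labelled siDnmt3a or siDnmt3b differed in methylation from those without siRNA. Whether either enzyme was lowered was not measured here. Both siRNA groups were slightly lower than the group without siRNA: 35.2% ± 0.350 (SD, n = 2) with siDnmt3a and 36.0% ± 1.78 (SD, n = 2) with siDnmt3b, against 38.1% ± 1.30 (SD, n = 3). The differences of -2.91 and -2.14 points gave exact permutation p-values of 0.2 and 0.3, where 0.1 is the smallest that 2 against 3 allow. They were -1.44 and -2.30 points over tiles covered in every library, with no overlap (exact permutation p = 0.2 and 0.1), and -5.33 and -5.87 points with pooled calls. The siDnmt3b difference was -3.40 and -0.883 points without siDnmt3b replicates 1 and 2. On the X the levels were 60.1% ± 1.15 and 60.8% ± 2.22 against 65.2% ± 0.799, lower by -5.11 and -4.37 points with no overlap (exact permutation p = 0.1 each). Tiles of low density were also apart, at 52.3% and 51.5% against 55.8%. EdgeR called 0 of 39439 tiles with siDnmt3a and 0 of 33937 with siDnmt3b, and limma called 0. At an unadjusted p under 0.05 there were 784 higher and 730 lower tiles with siDnmt3a, and 515 higher and 854 lower with siDnmt3b. In simulated data for the siDnmt3a comparison a shift of 80 points was recovered in 57% of changed tiles and one of 40 points in 0%. The 0 calls thus do not exclude changes at single tiles.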

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

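The tests between the lineages, the autosomal comparison, the bound set on the planned comparison over common sites and the minimum of 1000 mitochondrial calls were chosen only after the results were seen. The effect of cloning differed between trophectoderm and inner cell mass by 12.9 percentage points in mean CpG methylation and by 23.7 points on the X chromosome (exact permutation p = 0.005 for both). The effect of the demethylases differed between the same lineages by -11.6 points with Kdm5b and -11.5 points with Kdm4b+Kdm5b in mean CpG methylation. On the X it differed by -21.2 points with Kdm4b, -22.0 with Kdm5b and -24.4 with Kdm4b+Kdm5b. All of these were singled out because the effect of the same contrast differed between groups in a test of that difference. They are not independent, since each uses the same 3 cloned trophectoderm and 3 cloned inner cell mass libraries. The p-values take the libraries of the lineages as coming from separate embryos, which the labels do not state.

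Cloned trophectoderm enters all of these differences, though with Kdm5b part came from the inner cell mass (5.05 points, but 1.76 over tiles covered in every library, where the trophectoderm part was -13.5). For the higher methylation of cloned than of fertilised trophectoderm, 3 explanations were argued against by the tables, the third only in part. Incomplete bisulfite conversion would add methylated calls everywhere. Over 7960 tiles below 1% in the fertilised inner cell mass, however, cloned trophectoderm was 2.48 points higher (3.52% against 1.04%), with a median difference of 0.513 points, while the excess at low density was 26.1 points. A difference in the sites that each library covers was argued against by 48278 tiles covered in all 6 libraries, where the difference was 14.5 points. Different shares of male and female embryos, if they acted only on the X, would leave the autosomes alike. The autosomes alone differed by 10.6 points (21.9% against 11.3%). An effect of sex on the autosomes was not tested. The autosomal comparison also does not cover the gap on the X itself. Calls on the Y were fewer in every cloned than in every fertilised library of both lineages. At the 1-cell stage they overlapped, with 150 to 238 ppm in unmodified clones and 164 to 395 in fertilised embryos. In Kdm4b 4-cell clones they ran from 69.4 to 343 ppm. Whether calls on the Y measure sex here was not tested, and a different sex composition stays open for the X values.

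Donor-type somatic DNA carried into the cloned trophectoderm libraries cannot be told apart from methylation of the embryo. A fixed share of such DNA would give about the same level at tiles that are almost fully methylated in cloned 1-cell embryos and almost unmethylated in fertilised trophectoderm. At the 39 such tiles the SD between tiles, after subtracting the spread between libraries, was 17.6 points (95% interval 12.7 to 21.2), which lay between the outcomes that would have decided it, and too few tiles were covered. The levels there ran from 33.4% to 83.3% between the 10th and 90th percentiles. No library of donor cells was analysed here. A difference in remethylation between the embryo types, which the design names, may also account for the pattern and stays open.

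The tiles called higher in cloned trophectoderm had a history in the clones. In cloned 1-cell embryos they were 26.0 points above tiles matched for CpG number and for fertilised trophectoderm level (79.7% against 53.6%, 788 tiles covered in all 3 libraries, 95% interval 23.7 to 28.5), a test that could have come out the other way. The clones' excess in the inner cell mass was 16.97 points larger at these tiles than at matched ones (19.1 against 2.10 points, 2605 tiles, 95% interval 16.2 to 17.8). These values are consistent with methylation of the donor genome being kept or regained at the same places in both lineages. They do not tell keeping from regaining. Carried-over donor DNA would give the first value too. It would also give the second if the cloned inner cell mass libraries held some, which was not tested. Tiles are not independent replicates, so the intervals cover the choice of tiles and not the choice of embryos.

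Outside the main measurement, methylation of mitochondrial CpGs was 30.8% of 4009 calls in replicate 6 of the arrested clones, while the highest fertilised library with 1000 calls or more, 1-cell replicate 3, was at 12.0% of 3311 calls. With fewer calls, fertilised inner cell mass replicate 3 was at 28.7% of 387. Above 12.0%, with at least 1000 calls, were also replicate 2 of siDnmt3a (19.3% of 4886 calls), replicate 2 of siDnmt3b (18.4% of 1439) and replicate 3 of the unmodified 1-cell clones (12.8% of 2583). No explanation of this signal was tested, biological or technical. The test for a library far from the others of its group was made only in groups of 4 to 10 libraries, for mean and X methylation, and found 0 in 20 tests. Groups of 2 or 3 were not tested, among them Kdm4b+Kdm5b inner cell mass, whose replicate 3 was at 22.3% (X 42.4%) against 12.1% and 12.7% (X 20.2% and 23.4%).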

How the results depend on the processing

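The means over tiles shared by each pair of libraries and all alternatives of the tests between the lineages were chosen only after the data were seen. Of the 38 mean differences, overall or between the lineages, all 38 kept direction and call at a CpG coverage minimum of 10. With that minimum, tile calls were 1590 for clones against fertilised embryos in the trophectoderm (3163 in the report), 336 for Kdm5b there (212) and 6 for Kdm4b from 2-cell to 4-cell (1); the other 17 counts stayed within 1.5 times. A tile minimum of 30 calls gave 1980 and 3 for the first and last of these. Tiles of 1000 bp gave 1 for clones in the inner cell mass, 81 for Kdm5b and 5771 for Kdm4b+Kdm5b in the trophectoderm, and 165 and 38 for Kdm4b and Kdm4b+Kdm5b against arrested clones. The limma test gave 6221 in the trophectoderm for clones, 17769, 0 and 14104 for Kdm4b, Kdm5b and Kdm4b+Kdm5b, 140 for Kdm4b+Kdm5b against arrested clones and 0 for Kdm4b from 2-cell to 4-cell. The cause of these changes was not tested.

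In the 20 tile comparisons, the tile deviations of same-numbered libraries from their group means had correlations of -0.167 to 0.0932. The numbers were therefore not taken to pair the libraries. No correlation between inner cell mass and trophectoderm libraries was computed. With the replicate number as a block, calls were 1352 at the 1-cell stage, 3540, 733 and 856 for Kdm4b, Kdm5b and Kdm4b+Kdm5b in the trophectoderm, 0 and 45 for Kdm4b and Kdm4b+Kdm5b against arrested clones, and 0 for Kdm4b from 2-cell to 4-cell. The block moved no other count by over 1.5 times and no mean by more than its spread, although the small differences of Kdm4b and Kdm4b+Kdm5b from fertilised trophectoderm changed sign (-0.165 and -0.707 points). Of the named tiles, 19 lost their call with the block and 15 kept it. By limma 5 of them lost it and 29 kept it.

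The sites compared mattered most for the early stages. Over tiles covered in every library, differences reversed for Kdm4b and Kdm5b against arrested clones (-11.2 and -3.17 points), for Kdm4b and Kdm4b+Kdm5b from 2-cell to 4-cell (-5.79 and -3.75), and for Kdm4b and Kdm4b+Kdm5b against fertilised trophectoderm (-1.32 and -3.10). In the inner cell mass, clones against fertilised embryos (-1.80 to 0.458, at intermediate density to 0.296) and Kdm4b+Kdm5b against unmodified clones (0.577 to -1.58, at high density to -0.224) also changed sign, as did Kdm4b+Kdm5b on the X at the 1-cell stage (to 0.162). Others moved: clones against fertilised embryos to 18.8 at the 1-cell stage and 14.5 in the trophectoderm, the 1-cell demethylase groups against fertilised embryos to 13.4, 13.6 and 21.1, siDnmt3a to -1.44, and cloned inner cell mass against trophectoderm to -10.5. By density, those reversed were low density for Kdm4b against arrested clones (-8.10) and Kdm5b from 2-cell to 4-cell (2.72). At intermediate density they were Kdm4b, Kdm5b and Kdm4b+Kdm5b from 2-cell to 4-cell (-5.73, 0.577 and -3.74), and at high density Kdm4b and Kdm5b against arrested clones (-11.7 and -4.09) and Kdm4b and Kdm4b+Kdm5b from 2-cell to 4-cell (-8.39 and -4.71). On the X the last 2 contrasts reversed as well (-6.85 and -7.49). Over tiles shared by each pair of libraries, means moved to 0.667 and 15.5 for clones against fertilised embryos in the inner cell mass and trophectoderm, and to -17.6, -14.2 and -19.9 for the demethylases in the trophectoderm. They moved to -5.14 for Kdm4b against arrested clones, -0.234 and 0.366 for Kdm4b and Kdm5b from 2-cell to 4-cell, -1.50 for siDnmt3a, 10.1 for Kdm4b against fertilised 1-cell embryos, -0.974 and -2.99 for Kdm4b and Kdm4b+Kdm5b against fertilised trophectoderm, and -11.1 and 4.70 between inner cell mass and trophectoderm in unmodified and Kdm4b clones. Kdm4b+Kdm5b in the inner cell mass (-1.64) and Kdm5b against arrested clones (-0.674) changed sign as well.

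Pooled calls moved the clone effect to 16.3 at the 1-cell stage and 13.0 in the trophectoderm, Kdm4b+Kdm5b at the 1-cell stage from 1.96 to -6.60, siDnmt3a and siDnmt3b to -5.33 and -5.87, and fertilised inner cell mass against trophectoderm to 8.30. They reversed Kdm5b against arrested clones (-0.141), Kdm4b+Kdm5b from 2-cell to 4-cell (-0.387) and Kdm4b+Kdm5b in the inner cell mass (-0.591), and with them the Kdm4b+Kdm5b difference between lineages no longer passed (-11.2). A coverage minimum of 1 reversed Kdm4b+Kdm5b from 2-cell to 4-cell (-1.58) and against fertilised trophectoderm (-0.662), and with it the Kdm4b difference between lineages passed (-11.5). The cause was not tested.

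Leaving out 1 library at a time gave called tiles of 1164 to 1924 at the 1-cell stage, 226 to 3141 for clones in the trophectoderm, 225 to 1374, 0 to 246 and 334 to 1700 for Kdm4b, Kdm5b and Kdm4b+Kdm5b there, 74 to 171 and 79 to 129 for Kdm4b and Kdm4b+Kdm5b against arrested clones, and 0 in every case for Kdm4b from 2-cell to 4-cell. Kdm4b+Kdm5b from 2-cell to 4-cell ran from -0.532 to 2.57, and the 2 libraries of Kdm4b inner cell mass set its differences from fertilised inner cell mass (-5.21 to 0.246) and from trophectoderm (-1.59 to 3.87). Small differences also changed sign within their spread: Kdm4b+Kdm5b against unmodified clones at the 1-cell stage (-3.32 to 5.32) and in the inner cell mass (-2.72 to 2.38), Kdm4b there (-3.41 to 2.04), and Kdm4b+Kdm5b against fertilised inner cell mass (-4.51 to 0.585) and trophectoderm (-0.885 to 0.964). Differences between lineages ran from -11.5 to -6.03 for Kdm4b, -13.3 to -8.22 for Kdm4b+Kdm5b and -27.7 to -14.6 for Kdm4b on the X. Tiles tested numbered 4179 to 10690 in the 2-cell and 4-cell comparisons other than those with siRNA (39439 and 33937), and 47707 or more in the blastocyst.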

Other observations

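All tests in this part were set out before the result they measure was seen, except the comparison over tiles shared by each pair of libraries and the reading of trophectoderm tiles in other groups. The difference between Kdm4b 4-cell clones and arrested clones was 6.08 points on each library's own sites and -11.2 points over tiles covered in all 9 libraries. Over tiles shared by each pair of libraries it was -5.14 points, so the positive value appears only where each library contributes its own sites. The tiles covered in all 9 libraries had 8.06 times the calls per CpG position of other tiles in the fertilised inner cell mass (2798 tiles), and a level there of 44.9% against 20.2%. Tiles covered in every shallow library are likely to have many calls elsewhere too, whatever their copy number. The ratio therefore cannot tell sequence present in many copies from tiles that are easily covered. Whether either difference describes single-copy regions alone stays open.

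Whether other splits of the same libraries give as many called tiles was tested on 2000 tiles per comparison. For clones against fertilised embryos, 1 of 10 splits did so at the 1-cell stage (313 tiles, highest other 0) and 1 of 10 in the trophectoderm (122 tiles, highest other 0), and 10 splits are too few for a share under 0.05. In the trophectoderm only the real grouping gave as many with Kdm4b (1 of 40 splits, 203 tiles, highest other 0), Kdm5b (1 of 40 splits, 15 tiles, highest other 1) and Kdm4b+Kdm5b (1 of 35 splits, 108 tiles, highest other 3). The same held against arrested clones with Kdm4b (1 of 40 splits, 89 tiles, highest other 0) and Kdm4b+Kdm5b (1 of 40 splits, 20 tiles, highest other 1). Such a share is the smallest these draws allow and was not adjusted over the 17 comparisons with splits. Chance is therefore not excluded by these counts. Where the real grouping called 0 of these tiles, every split gives as many, and the count says nothing about chance. This was so with Kdm5b against arrested clones (40 of 40 splits, 0 tiles, highest other 0) and in the inner cell mass with Kdm5b (35 of 35 splits, 0 tiles, highest other 0). It was also so from 2-cell to 4-cell with Kdm4b, Kdm5b and Kdm4b+Kdm5b (40 of 40 splits each, 0 tiles, highest other 0, 3 and 1). The inner cell mass of clones against fertilised embryos, the inner cell mass with Kdm4b+Kdm5b and the 3 demethylase comparisons at the 1-cell stage each gave 10 of 10 splits (0 tiles, highest other 0), for the same reason.

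The tiles called higher in cloned trophectoderm were also read in groups that took no part in their selection. Their mean, taken over the tiles that each library covered and then over libraries, was 71.6% in cloned and 19.7% in fertilised 1-cell embryos, and 68.8% in arrested clones. Over the 788 tiles covered in all 3 cloned 1-cell libraries that had a matched tile, the first was 79.7%. With Kdm4b, Kdm5b and Kdm4b+Kdm5b the inner cell mass stood at 29.1%, 35.2% and 28.8%, against 32.2% in unmodified clones. In Low Kdm4b+Kdm5b 4-cell clones it was 66.1%, and 61.8% and 61.7% with siDnmt3a and siDnmt3b. Libraries and groups thus do not share exactly the same tiles.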
